A study of Saccharomyces cerevisiae with 41 samples.

How the data were processed

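RNA from 41 yeast samples was hybridised to Affymetrix Yeast 2.0 arrays, 1 array per sample, in 6 strains before and after UV. The deposited table holds 1 value per probe set and array on the log2 scale, which the authors computed with GCRMA 2.10.0 in R 2.6.2 according to the submitters' processing notes. GCRMA subtracts background by probe sequence, normalizes arrays to a shared distribution and summarises the probes of each probe set. The values ran from 1.62 to 15.96, as log2 array signal does, and no further transformation was applied. The scanner settings and the hybridisation dates are not given in the sources used here.

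Of 10928 probe sets, 213 are controls or reporters, 7245 are listed with a gene in the probe annotation table and 3470 are not listed. Of those listed, 7244 have 1 gene and 1 has several. Symbols and coding lengths (introns included) came from the R64 gene table, in which 5498 probe sets matched a budding yeast gene; 1747 were listed with genes absent from it, since the array also carries fission yeast probe sets, and these were not tested. A probe set was tested if it reached 4 on the log2 scale on at least 2 arrays, which left out 118 as dim and kept 5380 for 5337 genes. For the 42 genes with several tested probe sets, the 1 with the highest mean over all arrays stands for the gene, while counts are of probe sets. The arrays' 95th percentile of fission yeast probe sets, a measure of background, was 2.12 to 2.19.

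Strain, time and replicate number were taken from the sample labels, and the deleted genes' own signal was checked against them. A linear model with 1 mean for each of the 21 groups was fitted to all 41 arrays with limma 3.58.1 in R 4.3.3, with 20 residual and 2.86 prior degrees of freedom. The group of 1 array, mig3 at 15 min, was assumed to vary like the others. From this fit came 38 contrasts: 15 UV responses (irradiated minus unirradiated in the same strain), 5 differences of an unirradiated deletion strain from WT, 12 differences of a UV response from that of WT, 4 of the double deletion strain from a single deletion strain and 2 of rad4 from rad23. Moderated statistics were adjusted by Benjamini-Hochberg over the 5380 probe sets of each contrast, and a probe set was called at an adjusted p under 0.05. The replicate numbers are not stated to pair arrays across times, so the fit had no replicate term.

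The 36 gene lists, the comparisons, the tests and the rule for naming genes were chosen before the data were examined. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 36 lists of a contrast, and again with the correlation estimated from the data. Of the 1368 list tests, 374 were called with the preset correlation and 9 of those were also called with the estimated one. In the response of snf1 minus that of WT at 30 min, the glucose-repressed list had a median of -0.05 but a mean of 0.42, and camera ranked it upward. Named are the deleted genes. For each contrast, also named are up to 10 called genes with the largest rise and up to 10 with the largest fall whose arrays do not overlap, or, for a difference between responses, whose sign was kept without any 1 array. From each list described come up to 4 members with the largest absolute change, and every member of the RNR, Snf1 and Mig, and marker gene lists. From the genes this rule allows, those whose call held without any 1 array were preferred, a choice made after their values were seen.

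The fit was tested on simulated data of the same layout. For the WT response at 30 min it recovered 37.3% of genes changed by 0.5, 80.6% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, and called 4 of 5180 unchanged genes. For the snf1 minus WT response at 60 min it recovered 7.5%, 44.8% and 93.9%, and called 4 of 5180. The simulation drew independent errors with 1 SD per probe set shared by all groups. In the data the SD of replicate differences at 60 min was 0.75 in WT and 0.19 in snf1. These rates therefore need not hold for that contrast.

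For overlaps of deletion effects, the covariance across genes was set beside 100 simulations with no effect and the same shared WT arrays, and, chosen after the values were seen, computed with 1 WT replicate number for each strain. Shared calls were set beside the number given by independence. Intervals of list medians and length slopes are 95% bootstrap intervals over genes from 2000 resamples. Alternatives tried were no filter, a filter on fission yeast background, quantile normalization, median centring, an intensity trend with a robust prior, array weights, the arrays of a contrast alone, a replicate block, and leaving out each array in turn. Quantile normalization moved the median of all genes by up to 0.107 on the log2 scale. The replicates are called biological replicates, and nothing used here says beyond this that they came from separate cultures, so the p-values measure only the spread between these samples.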

Results

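Transcript levels were measured on 41 arrays of total RNA from haploid budding yeast of the YPH499 background. The arrays fall into 21 groups of strain and time. Besides wild type (WT), 5 deletion strains lacked MIG3, SNF1, RAD23, RAD4, or both SNF1 and RAD23, and are called mig3, snf1, rad23, rad4 and snf1rad23 here. Snf1 is the yeast AMP-activated protein kinase, needed for the use of carbon sources other than glucose, and Mig3 is a zinc finger protein of the Mig repressor family. Rad4 and Rad23 form the complex that recognises damage in nucleotide excision repair, the pathway that removes UV photoproducts. Cultures in glucose-rich YPD at 30 °C and an OD600 of 1.0 received 100 J/m2 of UV-C in water, or a mock treatment, and irradiated cells recovered in fresh YPD. WT, mig3 and snf1 were sampled unirradiated and 15, 30 and 60 min after UV, and rad23, snf1rad23 and rad4 unirradiated and 30 and 60 min after UV. Each group had 2 arrays, except mig3 at 15 min, of which 1 array was used here.

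The comparisons ask how WT responds to UV, how each deletion alters transcript levels without damage, and whether each deletion alters the response to UV. Changes are differences on the log2 scale ± SE from the limma fit, with 2 arrays per group unless another number is given, and levels are log2 means ± SD (n = 2). The median log2 signal of the tested probe sets ranged from 10.63 to 10.77 between arrays, and the number of arrays limits the precision. No mock-treated arrays at 15, 30 or 60 min were among them, so each UV response also holds any effect of the passage through water into fresh medium. A difference in response between strains also holds any difference between their unirradiated levels.

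The deleted genes were near background in the strains that lack them. SNF1 signal was 2.09 to 2.74 on the 14 arrays of snf1 and snf1rad23 and 10.69 to 11.92 on the other 27. MIG3 was 1.97 to 1.98 on 7 mig3 arrays and 8.20 to 10.21 on the other 34, RAD23 was 1.91 to 2.14 on 12 arrays and 12.01 to 13.49 on the other 29, and RAD4 was 1.99 to 2.27 on 6 arrays and 7.59 to 9.13 on the other 35. HIS3, a common deletion marker, was at 13.55 ± 0.08 in unirradiated rad23 and 13.79 ± 0.07 in snf1rad23, and at background in WT (1.87). Some other group means lay within 0.2 of background, so changes from them are limits, not sizes: SHH3, SNO4, PAU21, RRT5 and SPR2 in unirradiated WT, SPR2 in unirradiated rad4, RRT5 and RGI2 in unirradiated snf1rad23, RGI2 in WT at 30 and 60 min, GAC1 in WT and rad4 at 30 min, and YKR041W in mig3 and WT at 15 min. Of the genes next to a deleted locus, ANP1 beside RAD23 fell by 0.67 ± 0.15 in rad23 (adjusted p = 0.00085), UTR4 on its other side rose by 0.39 ± 0.11 in the same strain (adjusted p = 0.00705), GCG1 beside RAD4 fell by 0.49 ± 0.14 in rad4 (adjusted p = 0.0332) and YDR476C beside SNF1 rose by 0.71 ± 0.19 in snf1rad23 (adjusted p = 0.00616). The other 8 neighbour tests had adjusted p from 0.0722 to 0.798.

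Replicate arrays differed most in WT at 60 min, where 780 probe sets were over 2-fold apart between the arrays, and in mig3 at 30 and 60 min, with 370 and 384. In the other groups of 2 arrays this number was 5 to 282. The 3′ minus 5′ signal of the control gene SPT15 (TATA-binding protein), which rises as RNA degrades, was 1.76 to 2.02 in the 6 groups of rad23 and snf1rad23 against 1.11 to 1.43 in the other 15 groups. The same measure of 2 other control genes did not separate these groups: it was 2.70 to 3.91 against 2.08 to 3.92 for SRB4, and 0.04 to 0.26 against -0.05 to 0.14 for ACT1. The mean signal of an 18S ribosomal RNA control was 7.64 to 12.19 in unirradiated groups and 10.03 to 14.52 after UV, and its SD between arrays was 3.34 in WT at 60 min and 3.54 and 3.15 in mig3 at 30 and 60 min. A score of time since UV was near 0 at 30 min and 1 at 60 min in the deletion strains other than mig3. WT at 60 min had 0.39 for replicate 1 and 1.15 for replicate 2. By this score replicate 1 lay nearer the WT arrays of 30 min (-0.08 and -0.17). Yet DUN1 (11.29 ± 0.03) and RNR3 (12.49 ± 0.52) stood above 30 min (10.61 ± 0.11 and 10.81 ± 0.25). RNR1 and RFX1 lay within their spread of it. Every result that uses WT at 60 min rests on these 2 arrays.

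**Figure D1:**
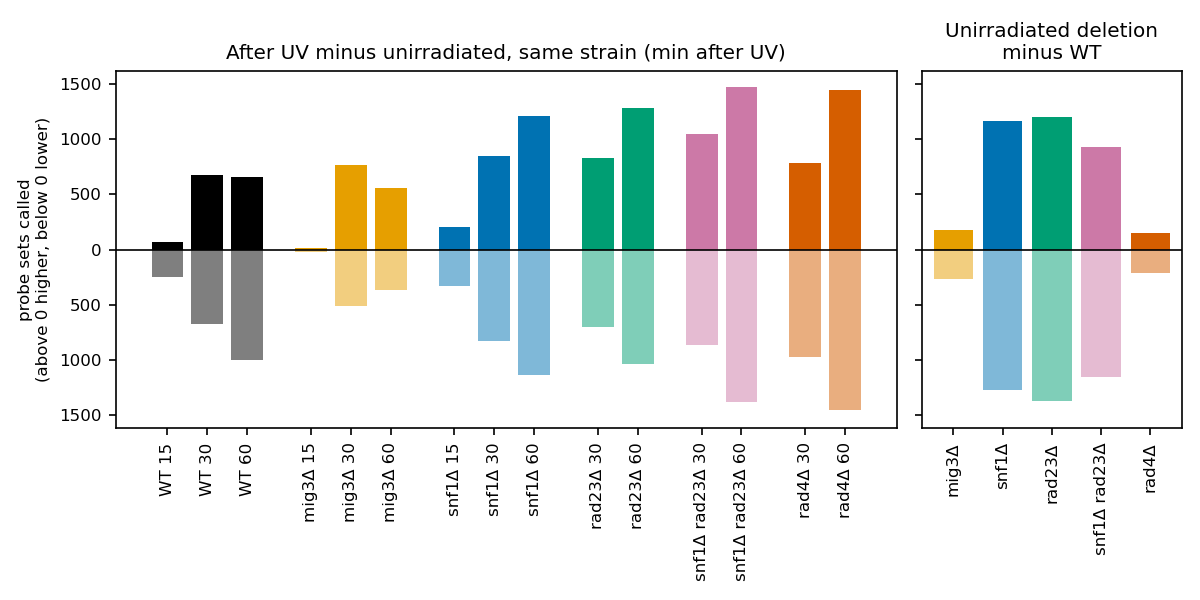
Number of probe sets called by limma (vertical axis) that were higher (above 0, full colour) or lower (below 0, pale) in each UV response against unirradiated cells of the same strain (left) and in each unirradiated deletion strain against WT (right). Among UV responses the count ran from 40 in mig3 at 15 min to 2895 in rad4 at 60 min.

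In WT 15 min after UV, some genes of the G2/M phase and mitotic exit fell. CLB2, the main mitotic cyclin, fell by 1.08 ± 0.20 and CDC5, the polo kinase, changed by -0.95 ± 0.13. Of that list 6 of 25 (9 adjusted over the list alone) fell and 1 rose (median -0.45, adjusted p = 1.54e-06, adjusted p = 1 with an estimated correlation). The largest falls kept without any 1 array were in ISF1 (-4.82 ± 0.61), GAC1, a regulatory subunit of the Glc7 phosphatase (-2.57 ± 0.47), WSC4, a cell wall sensor (-2.55 ± 0.43), and MTH1, a regulator of glucose transporter genes (-2.01 ± 0.40). YGR035C (3.07 ± 0.46), BAG7 (2.37 ± 0.39), the G1 cyclin PCL1 (2.08 ± 0.38) and the polyamine transporter TPO4 (1.71 ± 0.22) rose. In all, 318 probe sets were called, 71 higher and 247 lower. Quantile normalization gave 157, 80 higher and 77 lower, and median centring 94 higher and 149 lower, so the direction of the total depends on the scaling. The count was 190 or 93 without WT unirradiated replicate 1 or 2 and 82 or 149 without WT 15 min replicate 1 or 2. The calls on ISF1 and GAC1 ended with only the arrays of the contrast in the fit.

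By 30 min WT cells had induced the ribonucleotide reductase (RNR) and Crt1-repressed damage genes, and histone and mitotic transcripts had fallen. HUG1, which encodes an inhibitor of ribonucleotide reductase, rose by 2.23 ± 0.44, RNR3, a large subunit of the enzyme, by 2.01 ± 0.38, RFX1, which encodes the Crt1 repressor itself, by 1.17 ± 0.20 and the checkpoint kinase DUN1 by 0.85 ± 0.14. Of the RNR and Crt1 list 6 of 9 (7 adjusted over the list alone) rose (median 0.73, adjusted p = 0.00113, adjusted p = 0.325 with an estimated correlation). Of the histone genes 8 of 10 (9 adjusted over the list alone) fell (median -1.20, adjusted p = 3.38e-07, adjusted p = 0.134 with an estimated correlation). Members that fell include HTA1 (-1.85 ± 0.32), HTB2 (-1.59 ± 0.34) and HHT1 (-1.74 ± 0.18). G2/M genes fell for 14 of 25 (18 adjusted over the list alone) (median -0.75, adjusted p = 1.03e-05, adjusted p = 0.436 with an estimated correlation). Among them were CLB1 at -1.93 ± 0.26 and the spindle protein ASE1 at -2.18 ± 0.28. Methionine and sulfur genes rose for 11 of 29 (11 adjusted over the list alone) (median 0.47, adjusted p = 1.14e-04, adjusted p = 0.613 with an estimated correlation). The largest change was in the activator MET28 (4.87 ± 0.68). Phospholipid and inositol genes rose for 9 of 19 (10 adjusted over the list alone) and fell for 1 (median 0.43, adjusted p = 0.00762, adjusted p = 0.272 with an estimated correlation): INO1, the inositol synthase, was at 4.30 ± 0.66 and its activator INO2 at -2.35 ± 0.25. Mitochondrial ribosome genes fell for 29 of 69 (37 adjusted over the list alone) (median -0.50, adjusted p = 3.91e-10, adjusted p = 0.613 with an estimated correlation). Outside the lists, YPR015C (4.60 ± 0.39), BOP2 (3.40 ± 0.50) and ADH2, the ethanol-oxidising alcohol dehydrogenase (2.76 ± 0.46), rose, and ISF1 (-5.07 ± 0.61), HMS1 (-5.04 ± 0.52) and GAC1 (-4.62 ± 0.47) fell. The total was 1353, 677 higher and 676 lower. It was 720 without WT unirradiated replicate 2 and 691 or 836 without WT 30 min replicate 1 or 2.

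At 60 min damage genes were higher, and many ribosome biogenesis, histone and G2/M genes lower. HUG1 was up by 5.93 ± 0.44, RNR3 by 3.69 ± 0.38, PLM2 by 3.56 ± 0.31, DUN1 by 1.53 ± 0.14, DIN7, a DNA repair nuclease gene, by 1.28 ± 0.18, RNR2 by 0.72 ± 0.08 and RNR4 by 0.66 ± 0.09. The RNR and Crt1 list rose for 8 of 9 (8 adjusted over the list alone), and this call also held with the estimated correlation (median 1.08, adjusted p = 2.33e-09, adjusted p = 0.0196 with an estimated correlation). Ribosome biogenesis genes fell for 70 of 89 (79 adjusted over the list alone) (median -0.73, adjusted p = 8.52e-16, adjusted p = 0.577 with an estimated correlation). The member CIC1 was at -1.26 ± 0.13. Histone genes fell for 9 of 10 (9 adjusted over the list alone) (median -1.16, adjusted p = 1.17e-06, adjusted p = 0.117 with an estimated correlation), and the variant HTZ1 was at -1.38 ± 0.14. G2/M genes fell for 18 of 25 (20 adjusted over the list alone) (median -1.12, adjusted p = 4.63e-09, adjusted p = 0.216 with an estimated correlation). Among them were HOF1 at -2.56 ± 0.30 and CLB1 at -2.00 ± 0.26. General stress genes rose for 24 of 50 (25 adjusted over the list alone) and fell for 3 (median 0.76, adjusted p = 1.39e-06, adjusted p = 0.63 with an estimated correlation), HSP26 by 2.75 ± 0.38 and HSP12 by 2.73 ± 0.36, of which the call on HSP12 ended with array weights. That list's median was 1.18 without WT 60 min replicate 1 and 0.40 without replicate 2. Proteasome genes rose for 15 of 37 (18 adjusted over the list alone) (median 0.47, adjusted p = 3.79e-07, adjusted p = 0.63 with an estimated correlation), but without WT 60 min replicate 2 the median was 0.02 (adjusted p = 0.329) and without replicate 1 it was 0.89. HXT7, a high-affinity glucose transporter, fell by 3.84 ± 0.42 and MGA1 changed by -4.27 ± 0.40.

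The 60 min WT total was 1647 probe sets, 652 higher and 995 lower, and quantile normalization gave 816 higher and 806 lower, with median centring 826 and 799. It was 1090 or 963 without WT unirradiated replicate 1 or 2 and 941 without WT 60 min replicate 2. Array weights gave 248. With the WT unirradiated and 60 min arrays alone limma called 0, with 947 at an unadjusted p under 0.05, so the calls on HUG1, RNR3 and the other genes at 60 min rest on the spread borrowed from the other groups. Between times, 54 probe sets were called higher at both 15 and 30 min and 289 at both 30 and 60 min, and 159 and 336 were called lower.

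**Figure D2:**
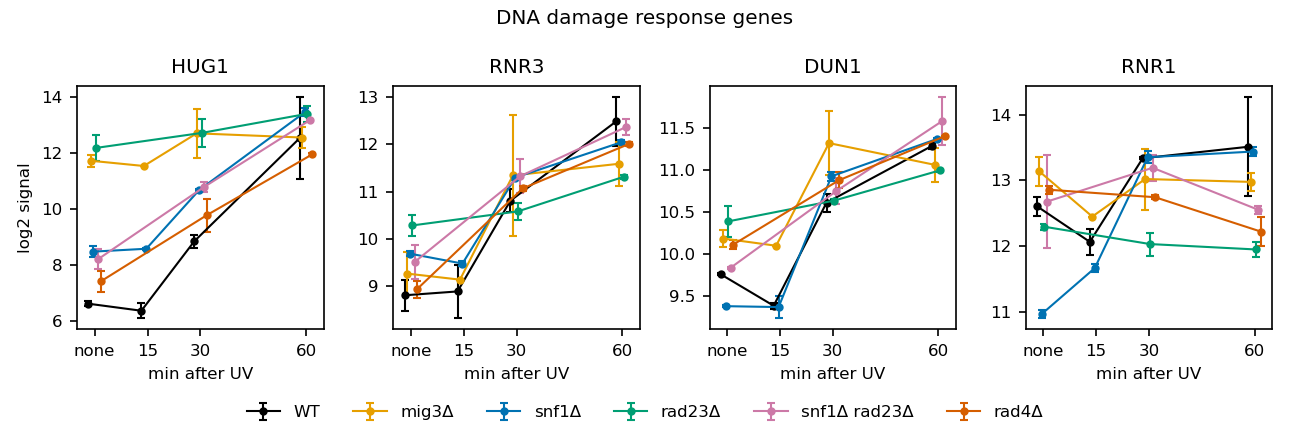
Log2 signal (vertical axes) of HUG1, RNR3, DUN1 and RNR1 against minutes after UV in the 6 strains, with means of 2 arrays as points offset sideways for legibility, SD as bars, and mig3 at 15 min as 1 array without a bar. Unirradiated HUG1 was 11.71 in mig3 and 12.17 in rad23 against 6.61 in WT.

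HUG1 started from different levels in the 6 strains and ended between 11.94 and 13.45. Unirradiated it was 6.61 ± 0.09 in WT, 11.71 ± 0.21 in mig3, 12.17 ± 0.45 in rad23, 8.47 ± 0.20 in snf1, 8.20 ± 0.36 in snf1rad23 and 7.41 ± 0.37 in rad4. At 60 min it was 12.53 ± 1.46, 12.54 ± 0.37, 13.39 ± 0.29, 13.45 ± 0.15, 13.16 ± 0.01 and 11.94 ± 0.05, in the same order of strains. Its rise over 60 min was smaller than in WT, differing by -5.10 ± 0.63 in mig3 and by -4.70 ± 0.63 in rad23. RNR3 was 8.80 ± 0.33 in unirradiated WT and 12.49 ± 0.52 at 60 min, and in rad23 10.28 ± 0.21 and 11.31 ± 0.05. RNR1, the constitutive large subunit, was 10.97 ± 0.07 in unirradiated snf1 against 12.61 ± 0.15 in WT, and 13.44 ± 0.07 in snf1 at 60 min.

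In unirradiated mig3 cells HUG1 and some stress genes were higher than in WT, and other stress genes were lower. HUG1 was up by 5.11 ± 0.44, the SUN family gene NCA3 by 4.07 ± 0.39, SNO4, a stress gene of the HSP31 family, by 4.29 ± 0.30, and HSP12, a small heat shock gene, by 2.53 ± 0.36. HMS1 (-4.08 ± 0.52), the glycogen synthase GSY1 (-2.87 ± 0.39), the catalase CTT1 (-2.50 ± 0.39) and the phosphatase PHO11 (-1.33 ± 0.28) were lower. Stress genes rose for 6 of 50 (8 adjusted over the list alone) and fell for 4 (median 0.33, adjusted p = 0.00129, adjusted p = 0.781 with an estimated correlation), with a median of 0.20 without mig3 unirradiated replicate 2. The RNR and Crt1 list rose for 2 of 9 (5 adjusted over the list alone) (median 0.43, adjusted p = 3.38e-05, adjusted p = 0.189 with an estimated correlation). G2/M genes rose for 3 of 25 (7 adjusted over the list alone) (median 0.33, adjusted p = 6.99e-05, adjusted p = 0.533 with an estimated correlation). The total was 447, 176 higher and 271 lower. Quantile normalization gave 215 higher and 170 lower, and median centring 237 and 189. The count was 161 or 177 without WT unirradiated replicate 1 or 2 and 227 or 142 without mig3 unirradiated replicate 1 or 2. With only the arrays of the contrast the count was 61, and the call on GSY1 ended.

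Loss of SNF1 moved 2436 probe sets without damage, 1164 higher, among them stress and glucose-repressed genes, and 1272 lower, among them ribosome biogenesis genes. Ribosome biogenesis genes fell for 76 of 89 (80 adjusted over the list alone) (median -0.83, adjusted p = 3.03e-15, adjusted p = 0.322 with an estimated correlation). G1/S genes fell for 27 of 36 (29 adjusted over the list alone) (median -1.02, adjusted p = 1.55e-07, adjusted p = 0.111 with an estimated correlation). Members include RNR1 at -1.64 ± 0.27. Mitochondrial ribosome genes fell for 40 of 69 (42 adjusted over the list alone) (median -0.57, adjusted p = 5.89e-08, adjusted p = 0.516 with an estimated correlation). Stress genes rose for 41 of 50 (43 adjusted over the list alone) (median 1.46, adjusted p = 1.70e-13, adjusted p = 0.264 with an estimated correlation). Oxidative phosphorylation genes rose for 30 of 34 (31 adjusted over the list alone) (median 0.59, adjusted p = 1.86e-10, adjusted p = 0.14 with an estimated correlation). The glucose-repressed list is also one of Snf1-dependent genes, and why it rose without SNF1 was not tested. It rose for 27 of 41 (30 adjusted over the list alone) while 2 fell (median 1.35, adjusted p = 3.55e-09, adjusted p = 0.119 with an estimated correlation). Genes of subtelomeric families rose for 21 of 28 (21 adjusted over the list alone) (median 1.11, adjusted p = 1.95e-09, adjusted p = 0.119 with an estimated correlation). Members include the flocculin FLO1 at 7.69 ± 0.30. Among regulators of glucose repression, MIG2 fell by 3.01 ± 0.37, while NRG1 rose by 2.20 ± 0.28 and TOS3, a kinase that activates Snf1, by 2.62 ± 0.17.

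**Figure D3:**
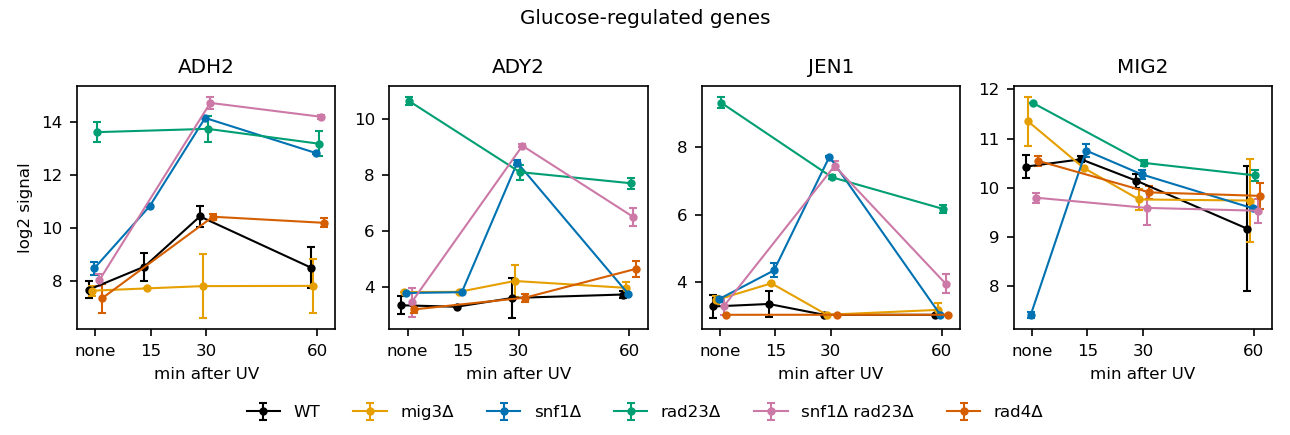
Log2 signal (vertical axes) of the glucose-regulated genes ADH2, ADY2, JEN1 and MIG2 against minutes after UV in the 6 strains, with means of 2 arrays as points offset sideways for legibility, SD as bars, and mig3 at 15 min as 1 array without a bar. Unirradiated ADY2 was 10.65 in rad23 and 3.34 in WT.

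Undamaged rad23 cells showed the largest median rise of glucose-repressed genes of the 5 deletion strains. The list rose for 36 of 41 (36 adjusted over the list alone), and the call held with the estimated correlation (median 2.46, adjusted p = 3.99e-21, adjusted p = 0.00506 with an estimated correlation). ADY2, an acetate transporter, was up by 7.30 ± 0.27, JEN1, a lactate transporter, by 6.04 ± 0.17 and MLS1, malate synthase, by 6.18 ± 0.45. Hexose transport genes rose for 11 of 15 (11 adjusted over the list alone) (median 1.68, adjusted p = 3.32e-04, adjusted p = 0.15 with an estimated correlation). Stress genes rose for 40 of 50 (41 adjusted over the list alone) (median 1.43, adjusted p = 7.86e-13, adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation genes rose for 28 of 34 (31 adjusted over the list alone) (median 0.61, adjusted p = 1.35e-10, adjusted p = 0.158 with an estimated correlation). Ribosome biogenesis genes fell for 62 of 89 (63 adjusted over the list alone) (median -0.64, adjusted p = 7.23e-10, adjusted p = 0.471 with an estimated correlation). HUG1 rose by 5.56 ± 0.44. Genes specific to the opposite mating type rose for 4 of 4 (4 adjusted over the list alone) (median 1.69, adjusted p = 0.00605, adjusted p = 0.252 with an estimated correlation). Among them were STE3, the a-factor receptor, at 3.18 ± 0.37 and SAG1, the alpha-agglutinin, at 2.13 ± 0.26. These strains also had the higher 3′ minus 5′ signal of SPT15, 1.98 ± 0.21 in unirradiated rad23 against 1.19 ± 0.04 in WT. The total was 2561, 1194 higher and 1367 lower. It was 1658 without WT unirradiated replicate 2 and 1699 without rad23 unirradiated replicate 2.

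With SNF1 deleted as well as RAD23, the glucose-repressed list also rose: 21 of 41 (22 adjusted over the list alone) rose and 3 fell (median 0.60, adjusted p = 2.18e-06, adjusted p = 0.166 with an estimated correlation). Besides HIS3, large rises in snf1rad23 were in SHH3 (7.91 ± 0.61), FLO1 (7.01 ± 0.30), DAK2, dihydroxyacetone kinase (6.64 ± 0.53), and FDH1, formate dehydrogenase (6.34 ± 0.44). Oxidative phosphorylation genes rose for 26 of 34 (29 adjusted over the list alone) (median 0.59, adjusted p = 2.58e-12, adjusted p = 0.102 with an estimated correlation). Mitochondrial ribosome genes fell for 41 of 69 (45 adjusted over the list alone) (median -0.56, adjusted p = 3.54e-08, adjusted p = 0.481 with an estimated correlation). GSY1 fell by 3.78 ± 0.39, MTH1 changed by -3.44 ± 0.40 and ISF1 changed by -3.21 ± 0.61. The 3′ minus 5′ signal of SPT15 was 1.90 ± 0.02 in unirradiated snf1rad23. The total was 2078, 929 higher and 1149 lower. It was 1127 without WT unirradiated replicate 2.

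Loss of RAD4 changed 363 probe sets without damage, 148 higher and 215 lower. Stress genes fell for 16 of 50 (22 adjusted over the list alone) (median -0.56, adjusted p = 9.66e-15, adjusted p = 0.969 with an estimated correlation). Members include GAC1 (-4.49 ± 0.47), RTN2 (-3.39 ± 0.60) and TMA10 (-3.29 ± 0.45). YNL194C (-6.69 ± 0.82), MGA1 (-4.82 ± 0.40) and SPG4 (-3.92 ± 0.58) also fell. COS8 (2.41 ± 0.22), HLR1 (2.07 ± 0.35), the repressor YHP1 (1.39 ± 0.21) and the G1 cyclin CLN1 (1.34 ± 0.20) rose. The count was 154 or 171 without WT unirradiated replicate 1 or 2 and 160 or 137 without rad4 unirradiated replicate 1 or 2. The call on HLR1 ended with only the arrays of the contrast in the fit.

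The differences of unirradiated snf1 and rad23 from WT overlapped. Across genes, which are not independent replicates, their differences from WT had a correlation of 0.61, where simulations without any effect but with the same shared WT arrays gave 0.50. Their covariance was 0.55 above the simulated one. With 1 WT replicate number for each strain, so that no WT array was shared, it was 0.54 or 0.58, depending on which strain took which. Both strains had 723 probe sets higher (258.3 if independent) and 658 lower (323.2), and 98 moved in opposite directions (578.1). For snf1 and mig3, 116 were higher in both (38.1) and 70 lower (64.1). For rad23 and rad4 the covariance was -0.06 against the simulated value without UV, but 0.16 above it for the UV responses at 60 min, where 122 probe sets responded more than in WT in both (39.4) and 118 less (27.1). With no WT array shared these covariances were 0.01 or -0.12 without UV and 0.19 or -0.04 at 60 min, so the sign of both depended on which WT arrays each strain took. The numbers of shared calls rest on shared WT arrays throughout. Of the 9 such pairs and times, the other covariance differences ran from -0.02 to 0.10.

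**Figure D4:**
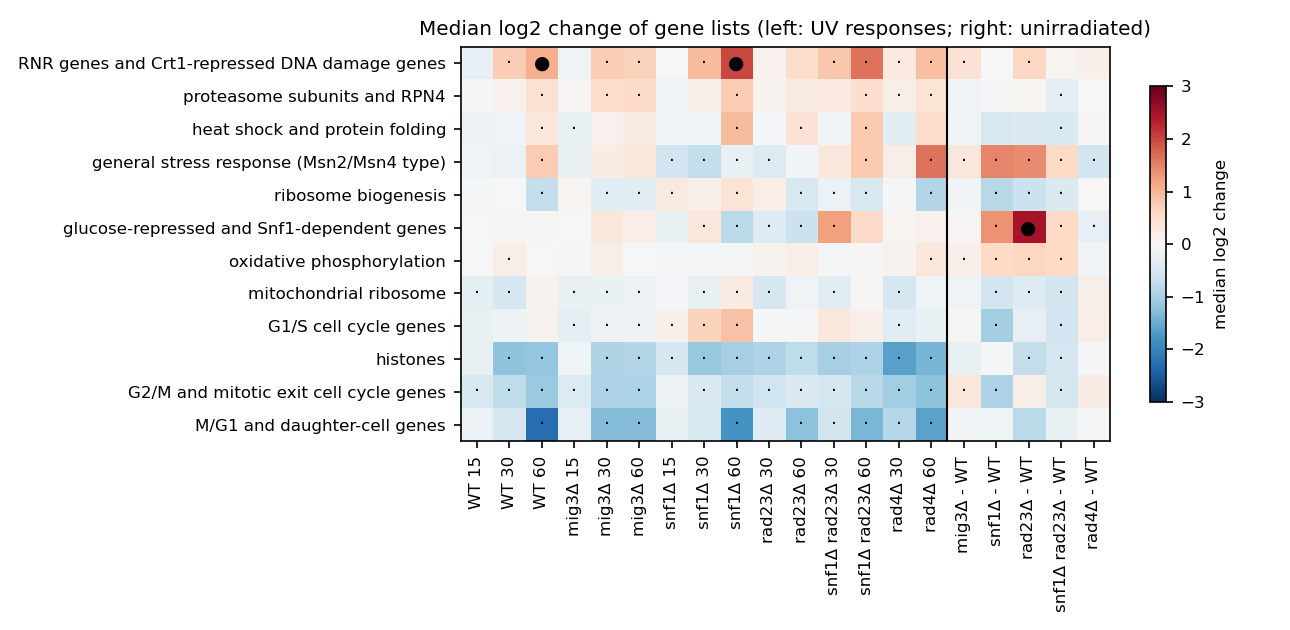
Median log2 change (colour) of 12 gene lists in the 15 UV responses (left) and the 5 unirradiated differences from WT (right). Small dots mark camera calls with the preset correlation and large dots those that also hold with an estimated one, which are the RNR and Crt1 list in WT and snf1 at 60 min and the glucose-repressed list in unirradiated rad23.

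In mig3 histone and G2/M transcripts fell after UV and DUN1 rose. At 15 min, with 1 array whose spread was taken from the other groups, 40 probe sets were called, among them FMP48 (2.76 ± 0.42) and TPO4 (2.27 ± 0.27) higher and INP2 (-1.56 ± 0.24) lower. At 30 and 60 min replicate 2 time labels may be exchanged, so means may mix times. The meiotic gene REC104 rose by 4.26 ± 0.67 and 4.10 ± 0.67, and YPR015C by 4.03 ± 0.39 and 3.89 ± 0.39. DUN1 rose by 1.14 ± 0.14 and 0.88 ± 0.14, and HTB2 fell by 2.37 ± 0.34 and 2.26 ± 0.34. Histone genes fell for 7 of 10 (8 adjusted over the list alone) at 30 min (median -0.89, adjusted p = 1.37e-06, adjusted p = 0.131 with an estimated correlation). At 60 min they fell for 8 of 10 (8 adjusted over the list alone) (median -0.87, adjusted p = 1.84e-07, adjusted p = 0.0717 with an estimated correlation). G2/M genes fell for 18 of 25 (19 adjusted over the list alone) (median -0.92, adjusted p = 1.39e-11, adjusted p = 0.131 with an estimated correlation) at 30 min. They fell for 18 of 25 (19 adjusted over the list alone) at 60 min (median -0.95, adjusted p = 3.93e-15, adjusted p = 0.0717 with an estimated correlation). Proteasome genes rose for 15 of 37 (27 adjusted over the list alone) at 30 min (median 0.52, adjusted p = 6.87e-07, adjusted p = 0.689 with an estimated correlation). The totals were 1269 and 915, 442 and 262 with array weights, and limma called 0 with the arrays of each contrast alone, with 1312 and 1207 at an unadjusted p under 0.05. The 15 min total was 14 higher and 26 lower, against 16 and 17 after quantile normalization. It was 21 or 11 without mig3 unirradiated replicate 1 or 2. The 30 min count was 610 or 468 without mig3 unirradiated replicate 1 or 2 and 813 without mig3 30 min replicate 2. The 60 min count was 359 or 308 without mig3 unirradiated replicate 1 or 2.

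The number of probe sets whose response differed between mig3 and WT depended on the arrays used. At 60 min the RNR and Crt1 list rose less than in WT, a difference that held with the estimated correlation (median -0.52, adjusted p = 3.58e-10, adjusted p = 0.0129 with an estimated correlation): 0 members were called more and 2 of 9 (6 adjusted over the list alone) less induced. The list stood higher in unirradiated mig3 (median 0.43), and this difference holds that start. Both 60 min groups hold an array of doubtful time. HUG1 (-5.10 ± 0.63), NCA3 (-3.86 ± 0.55) and HSP26 (-3.41 ± 0.54), all higher in unirradiated mig3, rose less, and HMS1 (4.33 ± 0.73), YMR084W (4.97 ± 0.76) and INO2 (2.27 ± 0.36) differed upward. At 30 min GSY1 (3.39 ± 0.56) and the proline oxidase PUT1 (2.82 ± 0.43) differed upward and YHP1 (-1.93 ± 0.30) downward. The interaction counts were 1 at 15 min, 51 at 30 min and 45 at 60 min. Of these, 37 and 29 were higher at 30 and 60 min, against 11 of 22 and 14 of 32 after quantile normalization and, at 60 min, 19 of 40 after median centring. A replicate block within strain gave 84 and 100. With only the arrays of each contrast limma called 0 at 30 and 60 min, with 690 and 262 at an unadjusted p under 0.05, and with array weights, which called 1 at 60 min, the only one of these named calls kept at 60 min was HUG1. The gene at 15 min, where mig3 has the same lone array, was YKR041W (1.88 ± 0.29), whose call was lost after quantile normalization, with a trend and robust prior, with only the arrays of the contrast, and without WT unirradiated replicate 2, WT 15 min replicate 2 or mig3 unirradiated replicate 2, where limma called 0, with 71, 81 and 36 at an unadjusted p under 0.05. The 30 min count was 22 or 20 without WT unirradiated replicate 1 or 2. It was 13 or 6 without WT 30 min replicate 1 or 2 and 9 without mig3 unirradiated replicate 2. It was 558 or 12 without mig3 30 min replicate 1 or 2. At 60 min it was 15 without WT unirradiated replicate 1 and 331 or 531 without WT 60 min replicate 1 or 2. It was 11 without mig3 unirradiated replicate 2 and 287 without mig3 60 min replicate 1.

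In snf1 the damage genes rose by 60 min, and single glucose-controlled genes changed from 15 min after UV and return to fresh medium. At 15 min MIG2, a glucose-induced repressor, rose by 3.34 ± 0.37, PCL1 by 3.21 ± 0.38, ADH2 by 2.35 ± 0.46 and the pyruvate carrier gene MPC3 by 2.21 ± 0.32, while HSP30 (-5.62 ± 0.83), GAC1 (-3.40 ± 0.47) and HXK1 (-1.86 ± 0.28) fell. Stress genes fell for 12 of 50 (13 adjusted over the list alone) (median -0.58, adjusted p = 9.47e-07, adjusted p = 0.972 with an estimated correlation). The glucose-repressed list had 4 higher and 6 lower at 15 min (median -0.19, adjusted p = 0.377, adjusted p = 0.972 with an estimated correlation) and rose at 30 min for 16 of 41 (16 adjusted over the list alone) while 7 fell (median 0.35, adjusted p = 0.0147, adjusted p = 0.81 with an estimated correlation). With only the arrays of the contrast in the fit the 30 min call ended. At 30 min ADH2 was up by 5.68 ± 0.46, ADY2 by 4.66 ± 0.27, JEN1 by 4.23 ± 0.17 and PLM2 by 4.12 ± 0.31, and HSP30 was down (-6.96 ± 0.83). G1/S genes rose for 19 of 36 (19 adjusted over the list alone) (median 0.68, adjusted p = 5.04e-06, adjusted p = 0.0812 with an estimated correlation). At 60 min RNR and Crt1 genes rose for 9 of 9 (9 adjusted over the list alone), and the call held with the estimated correlation (median 1.99, adjusted p = 1.11e-07, adjusted p = 0.0493 with an estimated correlation): HUG1 by 4.98 ± 0.44, RNR1 by 2.47 ± 0.27, RNR3 by 2.36 ± 0.38 and DUN1 by 1.99 ± 0.14. Proteasome genes rose for 34 of 37 (35 adjusted over the list alone) (median 0.76, adjusted p = 3.39e-08, adjusted p = 0.49 with an estimated correlation). Heat shock genes rose for 19 of 21 (19 adjusted over the list alone) (median 0.95, adjusted p = 1.25e-06, adjusted p = 0.49 with an estimated correlation). Members include BTN2 at 3.04 ± 0.65. Glucose-repressed genes fell for 23 of 41 (23 adjusted over the list alone) and rose for 4 (median -0.82, adjusted p = 2.68e-04, adjusted p = 0.49 with an estimated correlation). Members include POX1 at -4.32 ± 0.52. PHR1, the DNA photolyase, fell by 2.03 ± 0.35. The totals were 531, 1672 and 2339. At 15 min 205 were higher and 326 lower, against 277 and 254 after quantile normalization. The 15 min count was 194 or 210 without snf1 unirradiated replicate 1 or 2. It was 190 or 204 without snf1 15 min replicate 1 or 2. At 30 min it was 978 or 1024 without snf1 unirradiated replicate 1 or 2. It was 1018 or 943 without snf1 30 min replicate 1 or 2.

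Against WT, G1/S genes responded more in snf1 at 30 min, a call that held with the estimated correlation: 13 of 36 (17 adjusted over the list alone) (median 0.87, adjusted p = 1.02e-15, adjusted p = 0.00177 with an estimated correlation). At 60 min ribosome biogenesis genes differed upward for 75 of 89 (85 adjusted over the list alone) (median 1.13, adjusted p = 3.53e-28, adjusted p = 0.249 with an estimated correlation). Members include MAK16 at 2.08 ± 0.31. Stress genes differed downward for 24 of 50 (28 adjusted over the list alone) (median -1.18, adjusted p = 2.09e-13, adjusted p = 0.351 with an estimated correlation). Members include HSP12 at -2.67 ± 0.50. Glucose-repressed genes differed downward for 16 of 41 (19 adjusted over the list alone) and upward for 2 (median -0.88, adjusted p = 4.56e-07, adjusted p = 0.161 with an estimated correlation). Unirradiated snf1 differed from WT the other way in G1/S (median -1.02) and ribosome biogenesis genes (-0.83). The same was true of stress (1.46) and glucose-repressed genes (1.35). These differences in response therefore hold the different start. MIG2 differed by 3.19 ± 0.52, 3.14 ± 0.52 and 3.43 ± 0.52 at 15, 30 and 60 min, and RRN11, an RNA polymerase I factor, by 3.06 ± 0.30, 2.84 ± 0.30 and 2.64 ± 0.30. JEN1 (4.47 ± 0.24) and ADY2 (4.40 ± 0.39) responded more at 30 min, and FLO1 less at 30 and 60 min (-3.03 ± 0.43 and -5.19 ± 0.43). The interaction counts were 100, 219 and 1136. At 15 min 76 were higher and 24 lower, against 41 and 26 after median centring. The 15 min count was 34 without WT unirradiated replicate 2, 39 without WT 15 min replicate 1, 53 without WT 15 min replicate 2, 35 without snf1 unirradiated replicate 1, 33 without snf1 unirradiated replicate 2, 35 without snf1 15 min replicate 1 and 42 without snf1 15 min replicate 2. The count at 30 min was 121 without WT unirradiated replicate 2, 131 without WT 30 min replicate 1, 110 without snf1 unirradiated replicate 2, 130 without snf1 30 min replicate 1 and 133 without snf1 30 min replicate 2. At 60 min it was 712 without WT unirradiated replicate 2, 707 without snf1 unirradiated replicate 2 and 726 without snf1 60 min replicate 2, and 548 with array weights and 538 with only the arrays of the contrast.

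Some glucose-repressed genes of rad23 fell after UV and return to fresh medium. At 60 min the list fell for 19 of 41 (19 adjusted over the list alone) and rose for 1 (median -0.65, adjusted p = 2.21e-06, adjusted p = 0.685 with an estimated correlation), with MLS1 at -5.72 ± 0.45, ICL1, isocitrate lyase, at -3.71 ± 0.35 and JEN1 at -3.15 ± 0.17. Without rad23 unirradiated replicate 2 the median was -0.40. RGI2, a respiration gene, fell by 7.46 ± 0.17 at 30 min and fell by 7.08 ± 0.17 at 60 min. DUN1 rose by 0.61 ± 0.14 at 60 min. Histone genes fell for 6 of 10 (7 adjusted over the list alone) at 30 min (median -0.93, adjusted p = 4.13e-04, adjusted p = 0.594 with an estimated correlation). Mitochondrial ribosome genes fell for 33 of 69 (36 adjusted over the list alone) (median -0.51, adjusted p = 5.51e-11, adjusted p = 0.594 with an estimated correlation). At 60 min ribosome biogenesis genes fell for 42 of 89 (42 adjusted over the list alone) (median -0.47, adjusted p = 2.91e-07, adjusted p = 0.747 with an estimated correlation). TRA1, which encodes a large cofactor of SAGA and NuA4, fell by 3.47 ± 0.45 at 30 min and fell by 3.47 ± 0.45 at 60 min. REC104 (4.01 ± 0.67), PAU21 (3.81 ± 0.59) and SSP2 (3.12 ± 0.56) rose at 60 min. The totals were 1531 and 2315. The 30 min total was 937 without rad23 unirradiated replicate 1, 961 without rad23 unirradiated replicate 2 and 859 without rad23 30 min replicate 2.

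Set against WT at 60 min, the RNR and Crt1 list of rad23 responded less in 6 of 9 (7 adjusted over the list alone) and more in 1 (median -0.68, adjusted p = 6.26e-06, adjusted p = 0.0798 with an estimated correlation). Among them were HUG1 at -4.70 ± 0.63 and RNR3 at -2.66 ± 0.54. Glucose-repressed genes responded less for 16 of 41 (18 adjusted over the list alone) (median -1.03, adjusted p = 8.19e-12, adjusted p = 0.0798 with an estimated correlation). Members include MLS1 at -5.67 ± 0.64 and ADY2 at -3.33 ± 0.39. The RNR and Crt1 list and the glucose-repressed list stood higher in unirradiated rad23 than in WT (medians 0.63 and 2.46). The differences in response hold that start. The call on HUG1 ended with only the arrays of the contrast in the fit. RGI2 differed by -7.23 ± 0.24 and -6.87 ± 0.24 at 30 and 60 min. The endonuclease gene HO (4.02 ± 0.61), PAU21 (3.75 ± 0.84) and INO2 (2.74 ± 0.36) differed upward. The interaction counts were 181 and 762. At 60 min 463 were higher and 299 lower, against 371 and 412 after quantile normalization. The count at 30 min was 72 without WT unirradiated replicate 2 and 63 or 82 without WT 30 min replicate 1 or 2. It was 92 or 93 without rad23 unirradiated replicate 1 or 2 and 99 or 65 without rad23 30 min replicate 1 or 2. The count at 60 min was 499 or 455 without WT unirradiated replicate 1 or 2 and 1338 without WT 60 min replicate 2. It was 408 without rad23 unirradiated replicate 2 and 506 or 392 without rad23 60 min replicate 1 or 2. Array weights gave 92, and only the arrays of the contrast 83. The 3′ minus 5′ signal of SPT15 was 1.76 ± 0.03 and 1.94 ± 0.17 in rad23 at 30 and 60 min.

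The double deletion strain induced glucose-repressed genes together with the damage genes after UV. At 30 min the list rose for 27 of 41 (27 adjusted over the list alone) and fell for 2 (median 1.23, adjusted p = 8.49e-08, adjusted p = 0.341 with an estimated correlation): ADH2 by 6.69 ± 0.46, ADY2 by 5.60 ± 0.27 and JEN1 by 4.16 ± 0.17. The RNR and Crt1 list rose for 7 of 9 (7 adjusted over the list alone) at 30 min (median 0.80, adjusted p = 0.000998, adjusted p = 0.341 with an estimated correlation). At 60 min it rose for 7 of 9 (7 adjusted over the list alone) (median 1.63, adjusted p = 4.71e-05, adjusted p = 0.286 with an estimated correlation). HUG1 changed by 2.57 ± 0.44 and 4.96 ± 0.44. Heat shock genes rose for 16 of 21 (18 adjusted over the list alone) at 60 min (median 0.78, adjusted p = 3.31e-04, adjusted p = 0.824 with an estimated correlation). Members include SSA4 at 2.80 ± 0.60. MYO1, the type II myosin of the contractile ring, fell by 5.17 ± 0.62 and MOT1, a regulator of TATA-binding protein, changed by -3.63 ± 0.47 at 60 min. The 3′ minus 5′ signal of SPT15 was 1.81 ± 0.16 and 2.02 ± 0.20 at 30 and 60 min. The totals were 1912 and 2842. The 30 min count was 1074 without snf1rad23 30 min replicate 2.

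Against WT, the glucose-repressed list responded more in snf1rad23 at 30 min, a call that held with the estimated correlation: 16 of 41 (19 adjusted over the list alone) more and 1 less (median 1.10, adjusted p = 7.55e-14, adjusted p = 0.0413 with an estimated correlation). Members include ADY2 at 5.33 ± 0.39 and JEN1 at 4.41 ± 0.24. At 60 min ADH2 differed by 5.33 ± 0.65, RRT5 by 5.01 ± 0.77 and FLO1 by -3.44 ± 0.43, of which the call on RRT5 ended with array weights and with only the arrays of the contrast in the fit. The interaction counts were 170, with 107 higher and 63 lower against 86 and 79 after quantile normalization, and 1061, with 591 higher and 470 lower. The count at 30 min was 83 or 79 without WT unirradiated replicate 1 or 2. It was 80 or 57 without WT 30 min replicate 1 or 2 and 49 without snf1rad23 30 min replicate 2. At 60 min it was 601 without WT unirradiated replicate 1 and 1681 without WT 60 min replicate 2, and 64 with array weights and 11 with only the arrays of the contrast.

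Glucose-repressed genes responded upward in the double deletion strain relative to rad23. Their response was higher for 18 of 41 (25 adjusted over the list alone) at 30 min (median 1.50, adjusted p = 5.30e-27, adjusted p = 0.00122 with an estimated correlation). At 60 min it was higher for 14 of 41 (22 adjusted over the list alone) (median 1.29, adjusted p = 7.94e-14, adjusted p = 0.0415 with an estimated correlation). RGI2 differed by 10.15 ± 0.24, ADY2 by 8.14 ± 0.39 and ADH2 by 6.56 ± 0.65 at 30 min. The RNR and Crt1 list responded more at 60 min for 7 of 9 (7 adjusted over the list alone) (median 1.04, adjusted p = 6.60e-07, adjusted p = 0.0432 with an estimated correlation). Members include HUG1 at 3.74 ± 0.63 and DUN1 at 1.14 ± 0.20. These 3 list calls held with the estimated correlation, and the call on DUN1 ended with only the arrays of the contrast in the fit. Both lists started higher in rad23 (medians against WT 2.46 and 0.63) than in snf1rad23 (0.60 and 0.08), and the differences hold that start. HUG1 went from 12.17 to 13.39 in rad23 and from 8.20 to 13.16 in snf1rad23 at 60 min. The counts were 247 and 405. At 30 min it was 155 or 144 without rad23 unirradiated replicate 1 or 2. It was 126 or 120 without replicate 2 of rad23 or snf1rad23 at 30 min. At 60 min it was 191 without rad23 unirradiated replicate 2 and 207 or 209 without rad23 60 min replicate 1 or 2. It was 254 without snf1rad23 unirradiated replicate 1 and 209 or 729 without snf1rad23 60 min replicate 1 or 2.

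Against snf1, deleting RAD23 as well lowered the response of ribosome biogenesis genes at 60 min for 59 of 89 (61 adjusted over the list alone) (median -0.88, adjusted p = 4.45e-18, adjusted p = 0.457 with an estimated correlation). It raised the response of stress genes for 23 of 50 (28 adjusted over the list alone) (median 1.33, adjusted p = 7.21e-09, adjusted p = 0.605 with an estimated correlation). Glucose-repressed genes responded more for 23 of 41 (24 adjusted over the list alone) (median 1.16, adjusted p = 4.97e-06, adjusted p = 0.323 with an estimated correlation). SPS100, a spore wall gene, differed by 4.52 ± 0.50 at 30 min and 6.98 ± 0.50 at 60 min. Meiosis and sporulation genes differed upward for 15 of 26 (15 adjusted over the list alone) at 60 min (median 1.97, adjusted p = 4.45e-07, adjusted p = 0.323 with an estimated correlation). MIG2 differed by -3.07 ± 0.52 at 30 min and RNR1 by -2.60 ± 0.38 at 60 min. RNR1 started at 10.97 ± 0.07 in snf1 and 12.68 ± 0.71 in snf1rad23. The counts were 264 and 1723. The count at 30 min was 129 without snf1 unirradiated replicate 1, 67 without snf1 unirradiated replicate 2, 86 without snf1 30 min replicate 1, 90 without snf1 30 min replicate 2, 107 without snf1rad23 unirradiated replicate 1 and 83 without snf1rad23 30 min replicate 2.

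In rad4 the response to UV at 60 min had 2895 probe sets called, 1446 higher and 1449 lower. HUG1 rose by 2.36 ± 0.44 at 30 min and 4.54 ± 0.44 at 60 min, and RNR3 by 2.14 ± 0.38 and 3.08 ± 0.38. At 60 min the RNR and Crt1 list rose for 7 of 9 (7 adjusted over the list alone) and fell for 1 (median 0.90, adjusted p = 0.00145, adjusted p = 0.333 with an estimated correlation). Stress genes rose for 39 of 50 (40 adjusted over the list alone) (median 1.62, adjusted p = 5.90e-09, adjusted p = 0.769 with an estimated correlation). Members include the repressor XBP1 at 4.37 ± 0.77. Histone genes fell for 10 of 10 (10 adjusted over the list alone) (median -1.39, adjusted p = 1.25e-05, adjusted p = 0.333 with an estimated correlation), with HTA1 at -3.15 ± 0.32. G2/M genes fell for 22 of 25 (22 adjusted over the list alone) (median -1.23, adjusted p = 1.15e-08, adjusted p = 0.333 with an estimated correlation). Ribosome biogenesis genes fell for 65 of 89 (70 adjusted over the list alone) (median -0.88, adjusted p = 1.08e-11, adjusted p = 0.769 with an estimated correlation). MOT1 fell by 5.71 ± 0.47, MYO1 changed by -5.03 ± 0.62 and SNT2 changed by -3.77 ± 0.31, genes with coding lengths of 5604, 5787 and 4212 bp. Over 5324 genes with a coding length, without the 10 largest named falls relative to WT, the rad4 response at 60 min had a slope of -0.33 per doubling of that length (95% bootstrap interval -0.35 to -0.30), against -0.04 in WT, -0.03 in snf1, -0.26 in rad23 and -0.31 in snf1rad23. At 30 min histone genes fell for 8 of 10 (8 adjusted over the list alone) (median -1.64, adjusted p = 4.01e-07, adjusted p = 0.153 with an estimated correlation). The phosphate transporter PHO89 (4.55 ± 0.39), INO1 (4.52 ± 0.66) and MET28 (4.50 ± 0.68) rose. The 30 min total was 1746. It was 1055 or 1161 without rad4 unirradiated replicate 1 or 2.

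Against WT at 60 min, YNL194C (7.15 ± 1.16), RRT5 (5.70 ± 0.77), the spore wall gene SPR2 (5.28 ± 0.53) and CTT1 (3.98 ± 0.55) responded more in rad4, and MOT1 (-4.13 ± 0.66), SNT2 (-3.57 ± 0.44), AVO1, a TOR complex subunit (-3.54 ± 0.55), and SMC5, a chromosome maintenance gene (-2.32 ± 0.36), responded less. The calls on YNL194C, CTT1 and MOT1 ended with only the arrays of the contrast in the fit. At 30 min 44 probe sets were called, GAC1 at 4.21 ± 0.66. Of these 16 were higher and 28 lower, against 16 and 16 after median centring. YNL194C and GAC1 were already lower in unirradiated rad4 than in WT. The differences in their response at 60 and 30 min therefore hold that lower start, and need not mean a stronger induction by UV. Oxidative phosphorylation genes differed upward at 60 min for 6 of 34 (8 adjusted over the list alone) (median 0.33, adjusted p = 0.00856, adjusted p = 0.972 with an estimated correlation). This call was lost without rad4 unirradiated replicate 1 (median 0.24, adjusted p = 0.074). The 60 min count was 946. It was 598 without WT unirradiated replicate 1, 1718 without WT 60 min replicate 2, 518 without rad4 unirradiated replicate 1 and 488 without rad4 60 min replicate 2, and 261 with array weights and 178 with only the arrays of the contrast. At 30 min it was 16 without WT unirradiated replicate 1 or 2 and 9 or 10 without WT 30 min replicate 1 or 2. It was 4 or 23 without rad4 unirradiated replicate 1 or 2 and 21 without rad4 30 min replicate 2.

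The responses of rad4 and rad23, which lack partners of the same complex, differed in 318 probe sets at 30 min and 1009 at 60 min. At 60 min stress genes responded more in rad4 for 27 of 50 (38 adjusted over the list alone) (median 1.47, adjusted p = 4.89e-18, adjusted p = 0.392 with an estimated correlation). Members include CTT1 at 3.43 ± 0.55 and XBP1 at 4.63 ± 1.09. Glucose-repressed genes responded more for 21 of 41 (22 adjusted over the list alone) (median 1.15, adjusted p = 4.13e-12, adjusted p = 0.0811 with an estimated correlation). Members include MLS1 at 5.61 ± 0.64 and ADY2 at 4.39 ± 0.39. HUG1 (3.32 ± 0.63) and RNR3 (2.05 ± 0.54) rose more in rad4. G2/M genes responded less for 12 of 25 (13 adjusted over the list alone) (median -0.64, adjusted p = 6.64e-06, adjusted p = 0.392 with an estimated correlation). Members include ASE1 at -2.28 ± 0.40 and BUD4 at -2.38 ± 0.38. HO differed by -3.61 ± 0.61. The 30 min count was 146 without rad23 unirradiated replicate 1 and 200 or 133 without rad23 30 min replicate 1 or 2. It was 114 or 202 without rad4 unirradiated replicate 1 or 2 and 197 without rad4 30 min replicate 2. At 60 min it was 671 or 664 without replicate 2 of unirradiated or 60 min rad23. It was 591 without rad4 unirradiated replicate 1 and 536 without rad4 60 min replicate 2.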

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

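Tests of exchanged labels, recovery pace, glucose running low, Rad23 loss with and without Snf1, the trend with length and RNA degradation were chosen only after the results were seen; the tests of dim probe sets and of expression level were chosen before.

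Differences between strains in the response to UV, each tested as an interaction in limma, singled out 18 comparisons. Against WT the numbers of called probe sets were 1, 51 and 45 for mig3 at 15, 30 and 60 min, 100, 219 and 1136 for snf1, and at 30 and 60 min 181 and 762 for rad23, 170 and 1061 for snf1rad23, and 44 and 946 for rad4. The double deletion strain differed from snf1 in 264 and 1723 and from rad23 in 247 and 405, and rad4 differed from rad23 in 318 and 1009. No mock-treated arrays after matched times exist here, so a difference in the response to fresh medium would be counted too.

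Signals in data that the comparisons do not use were of 3 kinds. A reporter control probe set had at least 14.86 on all 20 arrays of snf1, snf1rad23 and rad4 and at most 1.96 on the other 21, which follows the strains. Of the probe sets listed with no gene, 214 reached the floor on at least 2 arrays. An 18S ribosomal RNA control probe set reached 14.63. What the reporter detects is not given in the sources used here.

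The mig3 arrays of 30 and 60 min differed between replicates along the time course. A score from 178 probe sets that rose or fell between 30 and 60 min in the other 4 deletion strains was 0.21 and 0.69 for replicates 1 and 2 of mig3 at 30 min, and 0.87 and 0.18 at 60 min, while the other 4 deletion strains ran from -0.19 to 0.34 and from 0.82 to 1.14, and WT had -0.08 and -0.17 at 30 min and 0.39 and 1.15 at 60 min. Replicate 2 recovering at another pace would shift both times the same way, and its shifts were 0.48 at 30 min and -0.69 (-0.6884) at 60 min, while replicates lay at most 0.15 apart in the other 4 deletion strains and 0.08 in WT at 30 min, yet this cannot be told apart, since the 2 WT arrays at 60 min, of which 1 has a doubtful time, lay 0.76 apart. An exchange of the time labels of the replicate 2 arrays remains open: over 5202 other probe sets the 60 minus 30 min difference had a correlation with the other deletion strains of 0.31 in replicate 1 and -0.37 (-0.3678) in replicate 2, against 0.23 and 0.68 in WT, so exchanged labels may be the source. No label was changed.

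Glucose-repressed genes stood 2.46 (95% interval 1.86 to 3.43) higher in unirradiated rad23 than in WT. Glucose running low before irradiation cannot be told apart: in fresh medium the difference was 1.77 (1.20 to 3.30) at 30 min and 1.63 (1.16 to 2.20; 1.632 before rounding) at 60 min, a change of -1.03 (-1.14 to -0.91) over 60 min, and no WT cells low in glucose show how fast these transcripts would fall. Dim probe sets lifted on these arrays are excluded, since the list lay at percentile 100 of 10000 random lists matched on expression, whose highest median was 1.01. Loss of Rad23 whether or not Snf1 is present cannot be told apart. The list did not rise in snf1rad23 minus snf1 (-0.33, -0.58 to -0.11 over genes). Yet it already stood 1.35 above WT in snf1, with 2 arrays per group. A Rad23 effect that needs Snf1 or a culture change unrelated to RAD23 may remain. The higher 3′ minus 5′ signal of SPT15 was not separated from these.

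Many long genes fell after UV in rad4. Over all genes but the 10 falls that drew attention to it, the slope of the rad4 minus WT response at 60 min on log2 coding length was -0.28 (-0.30 to -0.26; -0.282 before rounding), and in 4 length groups, from the shortest to the longest (at least 1911 bp), 165 of 1333, 231 of 1334, 322 of 1326 and 709 of 1331 were called lower after UV in rad4, against 178, 257, 232 and 314 in WT, and 141 of the longest were called higher in rad4. Expression level in place of length is excluded, since the slope was -0.29 (-0.2865) with level as a covariate. RNA degradation cannot be told apart: the 3′ minus 5′ signal changed in rad4 beyond WT by -0.09 (SE 0.14) for SPT15, -0.56 (SE 0.29) for SRB4 and -0.03 (SE 0.06) for ACT1, a mean of -0.22 (-0.2247, SE 0.12), within 2 standard errors of 0. Slopes of -0.21 in rad23 and -0.27 in snf1rad23 minus WT, against 0.01 in snf1, are in line with a trend shared by the repair-deficient strains, a hypothesis found and tested on the same data.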

How the results depend on the processing

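Alternatives fixed before the data were seen were the filters, the scalings, the prior, array weights, the arrays of a contrast alone, the replicate block and leaving out each array. The 4 chosen after seeing the data left out both mig3 arrays numbered 2 at 30 and 60 min, left out all arrays of WT at 60 min and mig3 at 30 and 60 min, added a replicate block within strain, or gave each strain of a pair 1 WT replicate number. Without a filter, with the fission yeast filter, with median centring and with the replicate block (paired by replicate number) all 38 counts stayed within 1.5 times. The replicate block gave 1696 for the WT response at 60 min. Counts that left that range are given next; the cause was not tested, except that fewer arrays leave fewer degrees of freedom. Quantile normalization gave 157 in WT at 15 min for UV responses. For responses minus that of WT they were 0 and 22 in mig3 at 15 and 30 min, and 29 in rad4 at 30 min. The trend with a robust prior gave 0 in mig3 minus WT at 15 min, where limma had 67 probe sets at an unadjusted p under 0.05, and quantile normalization had 63 there.

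Array weights gave 716, 2416 and 248 in WT at 15, 30 and 60 min, and 414, 442 and 262 in mig3 at 15, 30 and 60 min for UV responses. There were 2755, 3576 and 3708 in snf1 at 15, 30 and 60 min. Against WT without UV they were 951 in mig3 and 1145 in rad4. For responses minus that of WT they were 25 and 1 in mig3 at 30 and 60 min, and 661, 1222 and 548 in snf1 at 15, 30 and 60 min. There were 689 and 92 in rad23 at 30 and 60 min, and 64 in snf1rad23 at 60 min. There were 347 and 261 in rad4 at 30 and 60 min. Between deletion strains there were 630 in snf1rad23 minus snf1 at 30 min, and 247 in snf1rad23 minus rad23 at 60 min. There were 792 and 2099 in rad4 minus rad23 at 30 and 60 min.

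The arrays of the contrast alone gave 148 and 0 in WT at 15 and 60 min, and 0 and 0 in mig3 at 30 and 60 min for UV responses. There were 2229 and 3245 in snf1 at 15 and 30 min, and 1009 and 1453 in snf1rad23 at 30 and 60 min. Against WT without UV they were 61 in mig3 and 158 in rad4. For responses minus that of WT they were 0, 0 and 0 in mig3 at 15, 30 and 60 min, and 516, 917 and 538 in snf1 at 15, 30 and 60 min. There were 347 and 83 in rad23 at 30 and 60 min, and 94 and 11 in snf1rad23 at 30 and 60 min. There were 80 and 178 in rad4 at 30 and 60 min. Between deletion strains there were 151 and 133 in snf1rad23 minus rad23 at 30 and 60 min, and 1732 in rad4 minus rad23 at 60 min. Where limma called 0, the numbers at an unadjusted p under 0.05 were 947 for WT at 60 min, 1312 and 1207 for mig3 at 30 and 60 min, and 211, 690 and 262 for mig3 minus WT at 15, 30 and 60 min. The mig3 response at 15 min was left out of this alternative, which was set beforehand to need 2 residual degrees of freedom.

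Leaving out both mig3 arrays numbered 2 gave 119 in mig3 at 15 min for UV responses. Against WT without UV they were 547 in rad4. For responses minus that of WT they were 99 in mig3 at 60 min, and 183 and 348 in snf1 at 15 and 30 min. There were 356 in rad23 at 30 min, and 320 in snf1rad23 at 30 min. There were 92 in rad4 at 30 min. Between deletion strains there were 429 in snf1rad23 minus snf1 at 30 min, and 422 and 628 in snf1rad23 minus rad23 at 30 and 60 min. There were 482 in rad4 minus rad23 at 30 min.

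Leaving out all arrays of WT 60 min and mig3 30 and 60 min, possible for 29 contrasts, gave 667 and 2055 in WT at 15 and 30 min, and 259 in mig3 at 15 min for UV responses. There were 1105 in snf1 at 15 min. Against WT without UV they were 1000 in mig3 and 841 in rad4. For responses minus that of WT they were 313 and 562 in snf1 at 15 and 30 min, and 580 in rad23 at 30 min. There were 555 in snf1rad23 at 30 min, and 249 in rad4 at 30 min. Between deletion strains there were 800 in snf1rad23 minus snf1 at 30 min, and 655 and 1065 in snf1rad23 minus rad23 at 30 and 60 min. There were 800 and 1728 in rad4 minus rad23 at 30 and 60 min.

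The replicate block within strain gave 84 and 100 in mig3 at 30 and 60 min, and 280 in rad23 at 30 min for responses minus that of WT. There were 105 in rad4 at 30 min. Between deletion strains there were 421 in snf1rad23 minus snf1 at 30 min.

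Leaving out each array in turn, where a lone array is assumed to vary like the other groups, moved 129 of 220 counts beyond 1.5 times. The lowest and highest were 82 to 190, 691 to 985 and 941 to 2376 in WT at 15, 30 and 60 min, and 11 to 21, 468 to 1312 and 308 to 879 in mig3 at 15, 30 and 60 min for UV responses. There were 190 to 210, 943 to 1024 and 1568 to 1713 in snf1 at 15, 30 and 60 min, and 859 to 1021 and 1566 to 1670 in rad23 at 30 and 60 min. There were 1074 to 1748 and 2298 to 2392 in snf1rad23 at 30 and 60 min, and 1055 to 1254 and 2207 to 2471 in rad4 at 30 and 60 min. Against WT without UV they were 142 to 227 in mig3 and 1734 to 2124 in snf1. There were 1658 to 2315 in rad23 and 1127 to 1811 in snf1rad23. There were 137 to 171 in rad4. For responses minus that of WT they were 0 to 1, 6 to 558 and 11 to 531 in mig3 at 15, 30 and 60 min, and 33 to 68, 110 to 195 and 707 to 1548 in snf1 at 15, 30 and 60 min. There were 63 to 124 and 392 to 1338 in rad23 at 30 and 60 min, and 49 to 250 and 601 to 1681 in snf1rad23 at 30 and 60 min. There were 4 to 51 and 488 to 1718 in rad4 at 30 and 60 min. Between deletion strains there were 67 to 396 and 1160 to 1608 in snf1rad23 minus snf1 at 30 and 60 min, and 120 to 304 and 191 to 729 in snf1rad23 minus rad23 at 30 and 60 min. There were 114 to 245 and 536 to 899 in rad4 minus rad23 at 30 and 60 min.

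Without the filter the covariance of the unirradiated deletion effects above the simulated one was 0.5412 for snf1 and rad23 and -0.0611 for rad23 and rad4. With no WT array shared, as the mean of both ways to give out the WT arrays, it was 0.5603, 0.0854 and 0.0252 for snf1 and rad23, 0.0817, 0.0244 and -0.0797 for snf1 and mig3, -0.0549, 0.0517 and 0.0791 for rad23 and rad4 without UV and at 30 and 60 min. The mean turned sign for snf1 and mig3 at 30 min, and 1 of the 2 ways did for snf1 and rad23 at 60 min (-0.003), rad23 and rad4 at 60 min (-0.036) and rad23 and rad4 without UV (0.0117). List medians turned sign in 12 cases. Without WT 60 min replicate 1 the median was 0.108 for iron regulon in mig3 minus WT at 60 min (from -0.30, leave-one-array-out -0.67 to 0.11), 0.0261 for iron regulon in snf1 minus WT at 60 min (from -0.36, leave-one-array-out -0.74 to 0.03), 0.3193 for iron regulon in rad23 minus WT at 60 min (from -0.33, leave-one-array-out -0.62 to 0.32). Without WT 60 min replicate 2 the median was -0.0688 for heat shock and protein folding in the WT response at 60 min (from 0.33, leave-one-array-out -0.07 to 0.94), 0.0397 for ubiquitin pathway and shuttle factors in rad23 minus WT at 60 min (from -0.25, leave-one-array-out -0.64 to 0.04). Without mig3 30 min replicate 2 the median was 0.0141 for ribosome biogenesis in the mig3 response at 30 min (from -0.35, leave-one-array-out -0.79 to 0.01), 0.007 for RNA polymerase I and III in mig3 minus WT at 30 min (from -0.24, leave-one-array-out -0.50 to 0.01). Without mig3 60 min replicate 2 the median was 0.0401 for mitochondrial ribosome in mig3 minus WT at 60 min (from -0.29, leave-one-array-out -0.64 to 0.04). With the replicate block within strain the median was -0.0345 for iron regulon in unirradiated mig3 (from 0.31, leave-one-array-out 0.13 to 0.43). Leaving out both mig3 arrays gave the same 3 mig3 values as leaving out 1. The cause was not tested.

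Of 319 results of a list in a contrast followed through these settings, 9 were called with the estimated correlation and 310 were not. With the mean of a gene's probe sets 2 of 3 results of a gene in a contrast kept their call. Of 806 such results followed, 763 kept their call under quantile normalization, 745 with array weights, and 572 of 786 with the arrays of the contrast alone. Signal over background limits the dim genes: 118 probe sets never rose above the floor on 2 arrays, and a deleted gene at about 2 marks where a further fall cannot be seen.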

Other observations

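Several genes of no described group changed after UV in more than 1 strain. YPR015C, a zinc finger gene, rose at 60 min by 4.92 ± 0.39 in WT, 3.89 ± 0.39 in mig3, 6.37 ± 0.39 in snf1rad23 and 6.22 ± 0.39 in rad4. HMS1, a helix-loop-helix gene, changed at 60 min by -5.03 ± 0.52 in WT, -5.79 ± 0.52 in snf1, -3.81 ± 0.52 in rad23 and -4.05 ± 0.52 in snf1rad23. REC104, a gene of meiotic recombination, rose by 5.49 ± 0.67 in snf1rad23 and 5.76 ± 0.67 in rad4. RGS2, a regulator of G protein signalling, changed at 30 min by -3.05 ± 0.67 in mig3 and -3.25 ± 0.67 in snf1rad23. Whether these changes differ between the strains is stated only where an interaction is given in the results.

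Replicate 2 minus replicate 1 differences of groups of the same strain had correlations across genes with a median of 0.23 in 24 pairs of groups (-0.35 to 0.71), against 0.01 in 166 pairs from different strains. Genes are not independent replicates. The time score puts in doubt the time of WT 60 min replicate 1 and the mig3 replicate 2 labels at 30 and 60 min. Results without this WT array are given where it moved a count beyond 1.5 times.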
